A study of Mus musculus with 2 samples.

How the data were processed

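The series holds 2 single-cell RNA libraries from mouse sciatic nerve, 1 from uninjured nerves and 1 from the lesion 7 days after injury. Per the labels' protocols, nerves of several animals were pooled, chopped and digested at 37 degrees C, stained for CD45 and sorted for tdTomato-positive, CD45-negative cells. The matrices deposited by the authors hold counts of UMIs per gene and barcode with no normalization. Cell Ranger 3.0.2 made them, per the file headers, and Cell Ranger 6.1.2, Seurat 4.0.1 and the builds mm10 and GRCm38 are also listed, per the submitters' processing notes. A TdTomato sequence is among the 53380 features. The other 53379 are versioned Ensembl gene IDs, whose release is not given in the sources used here. Of all features 50604 (94.8%) had the same ID and version in a GENCODE annotation of GRCm38 and 53274 (99.8%) the same ID, and that annotation gave the positions. The authors also deposited a cell table with a class for 2301 cells. How those cells were filtered, checked for doublets or classed is not given in the sources used here.

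All barcodes of the matrices were read, and cells were matched to the authors' table by library and barcode. The intact library held 1618 barcodes and 9401203 UMIs, and the injured one 2023 barcodes and 27157892 UMIs, with at least 501 and 500 UMIs per barcode. Median mitochondrial shares were 5.10% and 3.83%, and the highest share of a barcode was 94.2% and 92.5%, but among annotated cells it was 19.6% and 19.8%. Annotated endothelial cells numbered 818 with 4615793 UMIs and 1322 with 20027884 UMIs. No further filter on cells was used in the main results. Scrublet, run per library through scanpy, called 3 of 1618 (0.185%) and 4 of 2023 (0.198%) barcodes doublets, of which 1 and 0 were annotated endothelial cells, and these were kept in the main results.

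Shares of cells carry exact Clopper-Pearson 95% intervals, and a share of 0 is given the limit of 3 counts. A ratio against 0 UMIs was computed against 3 counts over the group and is given as at least that value. For expression, UMIs were summed over the cells of a library and divided by their total to give CPM, with exact Poisson intervals. Ratios of CPM carry exact conditional binomial intervals, and log2 ratios had 5 CPM added to both values. A gene was measured at a mean of at least 10 CPM, which held for 8268 genes, and the Pearson correlation across genes of log2 CPM (5 CPM added) between the libraries was 0.882. With 1 library per condition no test was made, and animals, sorting and sequencing cannot be told apart from injury.

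Named genes were set by a rule written before the data were examined: the 12 highest and 12 lowest log2 ratios among genes with at least 50 CPM and 30 UMIs in the higher library, without mitochondrial, ribosomal protein, predicted (Gm and Rik), haemoglobin, immunoglobulin and control sex-linked genes. Up to 2 members in each direction were named per list, and 5 in each direction within classes that had at least 50 cells in both libraries, at 100 CPM or more. Names outside the rule are marked as such in the text. In the main comparison 27 biological gene lists and 1 control list of sex-linked genes, all fixed beforehand, were read as medians and as members at least 2-fold higher or lower. Each median was ranked among 10000 random lists drawn from 20 bins of expression, and its counting interval came from 1000 Poisson draws (seed 1).

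A class was checked by its 10 most enriched genes against other classes, at 100 CPM or more and at least 20 cells, and counted as failing where more of them were markers of another cell type than of its own. EC_IMMAT and INTERMEDIATE had no marker set of their own, so the check could not test these 2 names. Fixed marker sets of other and endothelial cell types were summed as CPM. Further sets in annotated cells were pan-endothelial (10402.5 and 7513.9 CPM), arterial (2069 and 1178), capillary (7928 and 4865), G2/M (71.1 and 782), S phase (288 and 623), platelet (13.9 and 20.6), adipocyte (2.73 and 0.246) and skeletal muscle (12 and 4.29). The DNA synthesis and mitosis lists are the same genes as the S phase and G2/M markers, and some genes, such as Tgfbi, Pfkfb3 and Slc2a1, stand in more than 1 list. Cycling cells were called from at least 2 different G2/M genes after thinning to 3000 UMIs by random draws without replacement. Own clusters were made from both libraries together, without aligning them, with 2000 variable genes, 30 principal components and Leiden resolution 1, giving 12 clusters. Taking each cluster as its largest class, 1559 of 2301 cells (67.8%) kept the authors' class.

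A shallower cell of a shared barcode was one whose barcode occurred in the other library with at least 5 times more UMIs. This step was added after the data were seen. Cells without a class and with at least 1000 UMIs were called fibroblast-like if they held at least 4 fibroblast marker genes and more fibroblast than pan-endothelial marker UMIs. They were called lymphatic-like if they held at least 4 lymphatic marker genes and more of those UMIs than fibroblast UMIs. These groups were also made after the data were seen and are used only after the report.

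The computation of the pooled comparison was tested on simulated data with known ratios over 8267 genes. Each simulated count was 1 Poisson draw per gene and library, with no cells, classes or animals. Coverage near 95% was therefore built in and does not measure variation between cells or animals. Planted ratios of 2 (50 genes), 4 (50 genes), 0.5 (47 genes) and 0.25 (45 genes) were recovered at medians of 1.97, 3.99, 0.487 and 0.253, and the 95% intervals covered 96%, 96%, 95.7% and 95.6% of them. For 8075 genes with no planted difference the median was 0.987 and coverage 95.4%. A planted list ranked at percentile 100, and 2 of 100 null lists fell outside the 2.5 to 97.5 percentile range.

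Alternatives fixed beforehand were all barcodes, scaling without mitochondrial, ribosomal protein and the 50 top genes, a median log2 ratio set to 0, the mean of per-cell CPM, thinning to 3000 UMIs, pseudocounts of 1 and 20 CPM, no filter on low values, a mean of at least 50 CPM, doublets left out, under 5% mitochondrial UMIs only, cells with G2/M genes left out, and classes weighted equally. Equal weights covered only classes with at least 20 cells in both libraries. Further alternatives were shares from own clusters or from cells of at least 3000 UMIs, and thinning to 2000 or 5000 UMIs or not at all, 1 or 3 G2/M genes, and the S phase list for cycling cells. Alternatives chosen after the data were seen were leaving out the shallower cells of shared barcodes, alone or together with the per-cell mean, equal class weights or, for class shares, those of similar depth, including the class INTERMEDIATE, and using only cells with Xist and no Y-linked UMI. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9. Raw reads were not analysed here. In addition, 1 gene within a class, 1 marker set and 1 alternative are not reported here.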

Results

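Blood vessels grow into a wounded nerve before axons cross it, and the endothelial cells that line them form a selective barrier in the resting nerve. The data collected here were RNA counts of single cells from adult mouse sciatic nerve, in which a Cdh5-driven, tamoxifen-inducible Cre had switched on a tdTomato reporter in endothelial cells. Cells were sorted as tdTomato-positive and CD45-negative from pooled uninjured nerves, called intact here, and from the bridge of tissue at the lesion 7 days after injury, called injured here. Each condition was 1 library of pooled animals, so there were no replicates, no test was made, and the 95% intervals given cover counting error only. They were exact for shares, CPM and ratios and simulated for list medians. The intact library held 1618 cell barcodes and 9401203 UMIs (unique molecules counted), with medians of 3932.5 UMIs and 1720.5 genes per cell. The injured library held 2023 barcodes and 27157892 UMIs, with medians of 8918 UMIs and 2991 genes. The authors' annotation covered 866 intact and 1435 injured cells in 10 classes, 9 of which were named as endothelial (818 and 1322 cells, with median depths of 3837 and 11104 UMIs). The remaining 752 intact and 588 injured barcodes had no class and were left out of the comparisons below.

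The 2 libraries shared 298 barcodes, and this bears on several class shares. In 116 of the pairs the intact cell was far shallower than its injured partner, with a mean of 1.33% of the partner's UMIs (standard deviation 0.0764 over pairs). In 145 pairs the injured cell was the shallower one, at a mean of 3.70% (standard deviation 0.247), and in 37 pairs the depths were similar. Values are given with all annotated cells first, and for class shares and named genes that moved most also without these shallower cells.

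**Figure D1:**
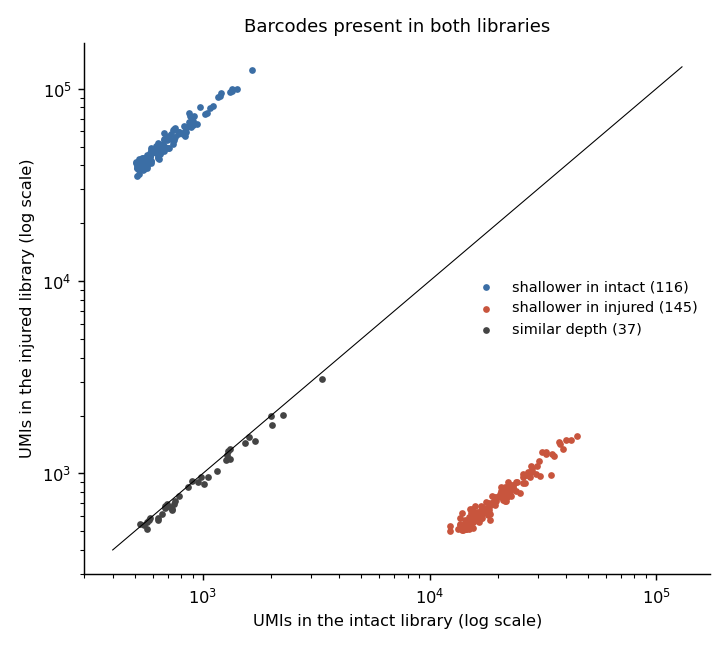
UMIs of each barcode found in both libraries, in the intact library (horizontal, UMIs, log scale) and in the injured library (vertical, UMIs, log scale), with the line of equality. 116 barcodes were shallower in the intact library, 145 were shallower in the injured library and 37 were similar, and the 2 shallower sets lay on narrow bands.

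The first question was how the authors' classes of annotated cells were divided in intact and in injured nerve. Arteries, capillaries and veins differ in the genes their endothelium expresses, and nerve endothelium adds a barrier type that carries nutrient and efflux transporters. After injury, sprouting vessels contain tip cells that lead the sprout and dividing cells that lengthen it. Plvap, which encodes the diaphragm protein of fenestrae and caveolae, is low in barrier vessels and high in leaky ones, and "PV" in the class names was not spelled out in the sources used here. The largest class in both libraries was EC_VEN-PV+, with 25.2% of annotated intact cells (218 of 866, interval 22.3 to 28.2%) and 25.2% of injured cells (362 of 1435, 23 to 27.6%). EC_ART likewise held near-equal shares, 10.7% (93 cells) and 10.0% (144 cells), a ratio of 0.934 (0.715 to 1.23), though own clusters gave 2.22. That value counts all of cluster 7 (12 intact and 140 injured cells) as EC_ART, its largest class at 40.8%. EC_BAR made up 20.9% of intact cells (181 cells, 18.2 to 23.8%) and 5.78% of injured cells (83 cells, 4.63 to 7.12%), a share 3.61-fold lower (2.77 to 4.74). Because 47 of the 83 injured EC_BAR cells were shallower partners of deeper intact cells, the share without such cells was 23.7% (181 cells) and 2.64% (36 cells), or 8.96-fold lower (6.24 to 13.2). EC_CAP-PV- held 14.9% of intact (129 cells) and 5.30% of injured cells (76 cells), a share 2.81-fold lower (2.10 to 3.79), though own clusters gave 193 intact and 3 injured cells, a ratio of 0.00938. Most injured EC_CAP-PV- cells (58 of 76) lay in cluster 3, which was counted as EC_IMMAT, its largest class at 33.7%. The ratio from own clusters thus depends on how clusters were named. EC_VEN-PV- held 5.08% (44 cells) and 8.43% (121 cells), a share 1.66-fold higher (1.17 to 2.40) in the injured library, but among cells of at least 3000 UMIs the shares were 8.96% and 9.29%, a ratio of 1.04.

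The 2 classes tied to vessel growth had larger shares after injury. EC_PROLIF made up 4.39% of intact (38 cells) and 11.3% of injured cells (162 cells), 2.57-fold higher (1.80 to 3.77), and 8.26-fold higher (4.50 to 16.9) once 27 shallower intact cells were left out. Of the 11 intact cells then left, 4 still had a barcode shared at similar depth, a set of barcodes with lymphoid markers at 6352 CPM in the intact library. With cells of that set left out too, 7 of 755 intact and 162 of 1354 injured cells remained, a ratio of 12.9. EC_TIP made up 2.42% (21 cells) and 6.97% (100 cells), 2.87-fold higher (1.78 to 4.85), and 14-fold higher (5.31 to 52.5) without 17 shallower intact cells. For 3 labels the marker check gave no match to the name, so only the share under the label is compared here. No marker set existed for EC_IMMAT or INTERMEDIATE, so the check could not test those 2 names. The label EC_IMMAT covered 6% of intact (52 cells) and 18.1% of injured cells (260 cells), a ratio of 3.02 (2.23 to 4.15), but 48 of the 52 intact cells were shallower partners, and without them the ratio was 36.5 (14.1 to 135) from 4 intact cells. The 10 most enriched genes of its injured cells held the capillary marker Rgcc and the venous marker Aplnr. Under the label EC_CAP-PV+ were 4.85% (42 cells) and 0.976% (14 cells), and its intact cells had 2 tip markers and 0 capillary markers among those genes. All 42 nevertheless fell into the own cluster that held 127 of 129 intact EC_CAP-PV- cells. The non-endothelial label INTERMEDIATE covered 5.54% (48 cells) and 7.87% (113 cells), with 2 fibroblast, 2 perineurial and 1 pericyte marker among those genes in intact and 2 myeloid and 2 fibroblast markers in injured cells, and its ratio of 1.42 became 0.677 in cells with under 5% mitochondrial UMIs. Of the 113 injured INTERMEDIATE cells 25 were shallower partners, and without shallower cells the ratio was 1.07 (0.743 to 1.57). The injured INTERMEDIATE cells also included 8 barcodes shared at similar depth, a set with the myeloid marker S100a9 at 1873 CPM in the injured library. Since transporter genes enriched in EC_BAR were themselves lower after injury, these shares describe the authors' labels and not numbers of vessels. The tdTomato sort sets which cells could be counted at all, and intact cells were less deeply covered.

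**Figure D2:**
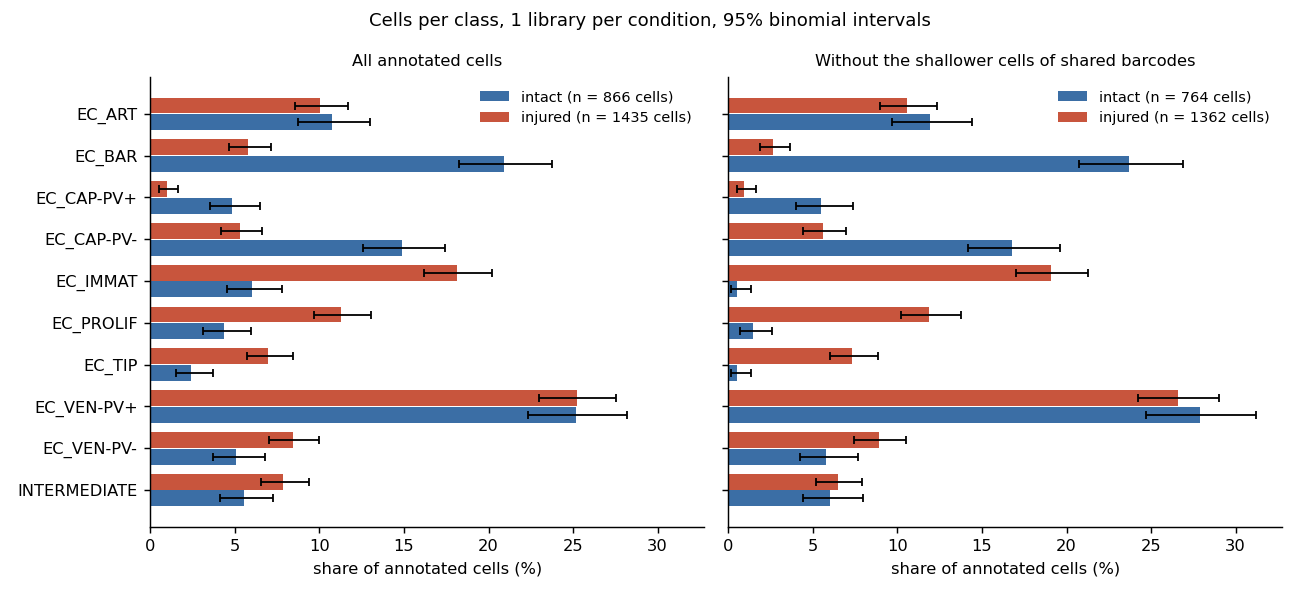
Percent of annotated cells in each of the authors' 10 classes in the intact and injured libraries (error bars, 95% binomial intervals), with all annotated cells (866 and 1435) and without the shallower cells of shared barcodes (764 and 1362). The injured share was lower for EC_BAR (20.9% and 5.78%) and higher for EC_TIP, EC_IMMAT and EC_PROLIF, by more without the shallower cells.

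The second question was which genes differed between endothelial cells of intact and injured nerve when all 9 endothelial classes were pooled. Endothelial cells of an uninjured vessel seldom divide, hold tight junctions and respond to flow. In a healing wound they enter the cell cycle, lay down basement membrane and loosen their contacts. Counts were summed over cells and scaled to the total of each library as CPM, and 8268 genes with a mean of at least 10 CPM were measured. Their median log2 ratio was 0.04, with the 10th percentile at -0.76 and the 90th at 0.71.

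Transcripts that identify the sorted cells came first. The reporter itself, TdTomato, stood at 79.7 CPM in intact and 96.4 CPM in injured endothelium, a ratio of 1.21 (1.08 to 1.36). Cdh5 (ENSMUSG00000031871.9), the adhesion molecule of endothelial junctions that drives the Cre, was at 837 and 1131 CPM, 1.35-fold higher (1.31 to 1.40). Pecam1, an adhesion molecule of the endothelial surface, was nearly level at 916 and 892 CPM (0.974, 0.941 to 1.01). The main VEGF receptor gene Kdr also stayed level, at 363 and 346 CPM (0.955, 0.905 to 1.01). By contrast Cldn5, the major claudin of endothelial tight junctions, was 4.45-fold lower (4.34 to 4.57; 2601 and 584 CPM). Slc2a1, which encodes the glucose transporter GLUT1, was 7.14-fold lower (6.67 to 7.65; 480 and 67.2 CPM). Plvap was 1.42-fold higher (1.37 to 1.47). The pools also differed in sex: Xist, expressed from the inactive X chromosome of females, was 3.19-fold higher at 294 and 938 CPM, and Y-linked Ddx3y fell from 55.2 to 20.1 CPM.

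Among the 12 genes with the largest higher ratios were secreted and surface proteins as well as cell-cycle genes. Mest (ENSMUSG00000051855.15, protein coding, GRCm38 chromosome 6, 30723547 to 30748465), an imprinted gene for a hydrolase-like membrane protein, was 17.3-fold higher (14.3 to 21.1; 23.6 and 409 CPM) and 42.3-fold higher (31.5 to 58.3) without the shallower cells. Chga (ENSMUSG00000021194.6, chromosome 12, 102554969 to 102565028), the secretory-granule protein chromogranin A, was 31.1-fold higher (19.6 to 52.5; 3.90 and 121 CPM). Without the shallower cells only 1 intact UMI of Chga remained, and its ratio was 552 (98.9 to 21792). Tgfbi (ENSMUSG00000035493.10, chromosome 13, 56609523 to 56639562), a matrix protein induced by TGF-beta, was 18.3-fold higher (14.1 to 24.2; 12.3 and 226 CPM), or 27.8-fold without the shallower cells. Cd276 (ENSMUSG00000035914.11, chromosome 9, 58524298 to 58555437), which encodes the immune checkpoint protein B7-H3, was 42.6-fold higher (19.5 to 116; 1.30 and 55.3 CPM), or 126-fold (34.8 to 1041) from 2 intact UMIs without the shallower cells. Marcksl1 (ENSMUSG00000047945.6), a regulator of actin and the cell membrane, was 11.3-fold higher (9.16 to 14.1). Mmp14 (ENSMUSG00000000957.11), a membrane-anchored matrix protease used by invading cells, was 10.2-fold higher (7.82 to 13.5). AA467197 (ENSMUSG00000033213.16) was 22.2-fold higher (13.2 to 40.8), or 38.3-fold without the shallower cells. The other 5 were genes of dividing cells. They were Cdk1 (ENSMUSG00000019942.13), the kinase that drives entry into mitosis (22.3-fold, 13.5 to 39.9), Ube2c (ENSMUSG00000001403.13), which serves the anaphase-promoting complex (17.5-fold, 11.7 to 27.4), Birc5 (ENSMUSG00000017716.15), a chromosomal passenger protein (15.2-fold, 10.3 to 23.6, and 23.4-fold without the shallower cells), Pclaf (ENSMUSG00000040204.6), a partner of the DNA clamp PCNA (14.5-fold, 9.91 to 22.0), and the replication histone Hist1h2ap (ENSMUSG00000094777.2; 10.4-fold, 8.78 to 12.4). Hist1h2ap belongs to a family of nearly identical histone copies, so its own value is uncertain. With cells expressing G2/M genes left out, Hist1h2ap and Pclaf were no longer higher (log2 ratios of -0.00 and -0.46), and Ube2c and Birc5 were at 0.45 and 0.18. The higher ratios also shrank with classes weighted equally, to log2 ratios of 0.84 for Mest, 1.00 for Chga, 1.35 for Tgfbi, 1.39 for Cd276, 0.24 for Ube2c and 0.05 for Birc5. With the shallower cells left out of the equal weights, these were 3.86, 3, 3.73, 2.28, 0.94 and 0.78. Those weights no longer covered EC_IMMAT, EC_PROLIF or EC_TIP, which had 4, 11 and 4 intact cells left. Over all barcodes, which include cells of other types, Tgfbi was at 0.57.

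Among the 12 genes with the lowest ratios were transporters, enzymes and secreted proteins. Slco1a4 (ENSMUSG00000030237.14, chromosome 6, 141805440 to 141856199), an organic anion transporter of barrier endothelium, was 54.5-fold lower (46.4 to 64.4; 435 and 7.99 CPM). Mfsd2a (ENSMUSG00000028655.11, chromosome 4, 122946850 to 122961188), which carries lysophospholipids and holds transcytosis low in brain vessels, was 32.0-fold lower (26.3 to 39.3; 181 and 5.64 CPM). Cytl1 (ENSMUSG00000062329.4, chromosome 5, 37735519 to 37739820), a small secreted protein, had the largest ratio of these at 84.1-fold lower (64.1 to 112; 231 and 2.75 CPM). Car4 (ENSMUSG00000000805.18), a carbonic anhydrase on the luminal surface of capillaries, was 47.1-fold lower (39.1 to 57.1; 289 and 6.14 CPM). Spock2 (ENSMUSG00000058297.16), an extracellular proteoglycan, was 27.3-fold lower (25.0 to 29.8; 804 and 29.5 CPM). Ptn (ENSMUSG00000029838.11), the heparin-binding growth factor pleiotrophin, was among the most abundant of these transcripts in intact endothelium, at 1073 CPM against 54.6 CPM, 19.6-fold lower (18.4 to 21.0). Hlf (ENSMUSG00000003949.16), a transcription factor of the PAR family under clock control, was 50.3-fold lower (35.6 to 73.3). The flavin-containing monooxygenases Fmo2 (ENSMUSG00000040170.13) and Fmo1 (ENSMUSG00000040181.14), which oxidise foreign compounds, were 28.2-fold (24.8 to 32.2) and 28.1-fold lower (22.1 to 36.2). Clic5 (ENSMUSG00000023959.8), a chloride intracellular channel protein linked to the cell cortex, was 23-fold lower (18.8 to 28.5), and Prom1 (ENSMUSG00000029086.15), a protein of membrane protrusions, 17.5-fold lower (15.3 to 20.1). Pcp4l1 (ENSMUSG00000038370.6) was 13.7-fold lower (12.6 to 14.9).

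The same pooled values were then read over gene lists fixed before the data were examined. A member counted as at least 2-fold higher or lower after 5 CPM were added to both values, and each list median was ranked among 10000 random lists of matched expression. Members named as examples had the highest or lowest ratios of their list, except Col4a1, Col4a2, Abcb1a, Slc7a5, Lef1, Tcf7, Sox17, Apln, Dll4, Klf2, Icam1, Sele, Vcam1, Isg15, Egr1 and Fos, which were chosen after their values were seen. Cell division moved most uniformly: 16 of 16 measured mitosis genes were at least 2-fold higher (median log2 ratio 2.25, percentile 100). With classes weighted equally the count was 1 and the median -0.02, and the count was 7 as a mean of per-cell CPM. Equal weights give EC_PROLIF the same weight in both libraries, and 27 of its 38 intact cells were shallower partners of injured cells. In 13 of the 15 alternatives with a value the count stayed near the main one. For DNA synthesis 10 of 15 genes were at least 2-fold higher, 0 lower and 5 between (median 1.10, percentile 100). With a mean of at least 50 CPM required the median was -0.43. Only 1 of the 15 had a log2 ratio below 0 in the main setting, so that median rests on very few genes. The count of 10 was 2 after thinning to 3000 UMIs, 1 as a mean of per-cell CPM and 0 with classes weighted equally. Mcm5, part of the replicative helicase, was 6.58-fold higher (4.42 to 10.2). Of 18 E2F and MYC response genes, 4 were at least 2-fold higher, 2 lower and 12 between (median 0.54), but 0 were higher as a mean of per-cell CPM or with classes weighted equally. Without the shallower cells the count was near 4 by per-cell means but stayed lower with equal weights. The 2 lower members were both cell-cycle regulators, the cyclin gene Ccnd2, which promotes G1 progression (10.0-fold lower), and Cdkn1a, the inhibitor p21 (2.62-fold lower).

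Basement membrane was the next group on the higher side. Of 20 measured basement membrane and matrix genes, 10 were at least 2-fold higher, 2 lower and 8 between (median 0.95, percentile 100). The count of 10 was 6 as a mean of per-cell CPM and 2 with classes weighted equally. It was 10 again with equal weights and no shallower cells, where EC_IMMAT, EC_PROLIF and EC_TIP had also dropped out. The paired collagen IV genes Col4a1 and Col4a2, which lie head to head on chromosome 8, were 5.54-fold (5.30 to 5.80; 437 and 2423 CPM) and 4.71-fold higher (4.47 to 4.97; 310 and 1463 CPM). Col18a1, the core protein from which endostatin is released, was 6.91-fold higher (6.27 to 7.64), and Lamb1, a laminin beta chain, 6.37-fold higher (5.38 to 7.61). The exceptions were Lamb2, the laminin beta chain of mature basement membrane (2.74-fold lower, 2.49 to 3.02), and Mgp, an inhibitor of calcification and BMP signals (2.08-fold lower, 1.99 to 2.16). Collagen processing and matrix proteases were more mixed, with 6 of 18 at least 2-fold higher, 2 lower and 10 between (median 0.37, percentile 98.4). Timp1, an inhibitor of matrix proteases, was 11.3-fold higher (7.83 to 16.9), while its relative Timp3 was 4.12-fold lower (3.95 to 4.29), and Plat, the tissue plasminogen activator, 3.89-fold lower (3.50 to 4.31).

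Genes of cell shape and movement followed. In the list of actin cytoskeleton and migration, 10 of 26 genes were at least 2-fold higher, 1 lower and 15 between (median 0.61, percentile 100), with 6 higher as a mean of per-cell CPM and 2 with classes weighted equally. Cotl1, an actin-binding protein of the coactosin family, was 9.57-fold higher (7.41 to 12.6), and Itga1, the collagen-binding integrin alpha chain, 2.27-fold lower (2.10 to 2.46). Without the shallower cells the actin count was near 10 again in both of these settings. Of 13 mesenchymal transition genes 3 were at least 2-fold higher, 2 lower and 8 between (median 0.56, percentile 99.6), but the median was -0.04 as a mean of per-cell CPM and -0.08 with classes weighted equally, where 1 was higher. Neither reversal appeared once the shallower cells were also left out, though equal weights then no longer covered EC_IMMAT, EC_PROLIF or EC_TIP. Vim, the intermediate filament vimentin, was 2.19-fold higher (2.15 to 2.23; 2763 and 6046 CPM), whereas the contractile genes Tagln and Acta2, both also marks of mural cells, were 4.05-fold (3.86 to 4.26) and 6.93-fold lower (6.38 to 7.52). These 2 genes belong to the pericyte and smooth muscle marker set, which stood at 1135 CPM in all annotated intact cells and 225 CPM in injured ones. The fall of that set is therefore partly their own and no separate sign of mural cells. YAP and TEAD targets, which respond to cell tension, had 0 of 11 genes beyond 2-fold either way (median -0.25, percentile 5.58). Amotl2, a junction protein of the angiomotin family, was 1.73-fold lower (1.56 to 1.92).

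Transporters of the blood-nerve barrier had the lowest pooled median of the lists. Of 17 measured barrier transporters 12 were at least 2-fold lower, 0 higher and 5 between (median -1.72, percentile 0). Besides Slco1a4 and Mfsd2a these included Slc7a5, the large neutral amino acid transporter (17.4-fold lower, 14.5 to 20.9), and Abcb1a, the efflux pump P-glycoprotein (5.73-fold lower, 5.42 to 6.05). Slc29a1, a nucleoside transporter, was 1.98-fold higher (1.73 to 2.26). Wnt and beta-catenin signalling, which induces barrier properties in brain endothelium, had 5 of 15 genes at least 2-fold lower and 0 higher (median -0.58, percentile 0.05), or 3 lower with classes weighted equally and 2 with a mean of at least 50 CPM required. The 5 included the feedback targets Nkd1 (31.6-fold, 21.8 to 47.3) and Axin2 (17.4-fold, 12.7 to 24.3) and the transcription factors Lef1 (8.20-fold, 6.98 to 9.64) and Tcf7 (4.74-fold, 3.75 to 5.99). Among 15 genes of endothelial junctions 5 were at least 2-fold lower and 0 higher (median -0.23, percentile 5.94), led by Lsr, the tricellular junction receptor angulin-1 (6.11-fold lower, 5.29 to 7.05), and Cldn5. Caveolae, transcytosis and fenestrae were nearly unshifted as a list, with 1 of 14 at least 2-fold higher, 1 lower and 12 between (median -0.00, percentile 27.2). Ehd3, which helps membrane recycling, was 2.51-fold higher (2.11 to 3), and Plpp3, a lipid phosphatase, 2.57-fold lower (2.46 to 2.68). Of 24 endothelial transcription factors 6 were at least 2-fold lower and 0 higher (median -0.44, percentile 0.03). Foxq1, a forkhead factor found in brain endothelium, was 35.0-fold lower (24.3 to 51.9), and Sox17, which acts in arterial and barrier development, 2.70-fold lower (2.57 to 2.84).

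Signals that guide vessel growth did not move as a block. Of 9 VEGF ligands and receptors 1 was at least 2-fold higher, 3 lower and 5 between (median -0.20, percentile 14.1). The higher one was Pgf, placental growth factor (7.69-fold, 4.25 to 15.5; 2.38 and 18.3 CPM), and lower ones included Flt1, the decoy receptor for VEGF-A (2.63-fold, 2.55 to 2.72), and Vegfc, a lymphatic growth factor (2.79-fold, 2.38 to 3.28). Angiopoietin, apelin and adrenomedullin signals had 3 of 9 at least 2-fold higher and 0 lower (median 0.29, percentile 80.8). These were the apelin receptor gene Aplnr (3.57-fold, 3.30 to 3.87), its ligand gene Apln (2.54-fold, 2.15 to 3.02) and Angpt2, a ligand that loosens vessels (2.74-fold, 2.28 to 3.31), while the receptor gene Tek was 1.53-fold lower (1.42 to 1.65). In the Notch pathway 5 of 11 genes were at least 2-fold lower and 0 higher (median -0.61, percentile 0.16). Among them were the target gene Hes1 (4.47-fold, 4.21 to 4.74), the ligand gene Dll4, which restrains tip cell formation (2.20-fold, 2.00 to 2.43), and Lfng, which modifies Notch receptors (2.41-fold, 2.12 to 2.74). The count of 5 in this list fell to between 1 and 3 in several other settings, although the median stayed below 0. For TGF-beta and BMP, 2 of 22 genes were at least 2-fold higher, 6 lower and 14 between (median -0.43, percentile 0.06). The 2 higher were Tgfbi and the ligand gene Bmp2 (4.62-fold, 3.32 to 6.62), and lower ones included the BMP targets Id1 (4.08-fold, 3.90 to 4.27) and Id3 (3.10-fold, 2.99 to 3.21). Of 22 axon guidance genes 4 were at least 2-fold lower and 0 higher (median -0.27, percentile 0.82), among them Epha4, an ephrin receptor (3.46-fold, 3.07 to 3.90), and Ntn4, a laminin-related netrin (4.04-fold, 3.12 to 5.22).

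Secreted growth factors and chemokines of endothelial cells had 4 of 20 genes at least 2-fold higher, 7 lower and 9 between (median -0.62, percentile 0). The count of 7 was 4 with 20 CPM added, 3 with classes weighted equally, and 2 over all barcodes or with a mean of at least 50 CPM required. Cxcl12, a chemokine that attracts leukocytes and progenitor cells, was 5.78-fold lower (5.6 to 5.97; 1914 and 331 CPM), and Ntf3, the neurotrophin NT-3 that sustains neurons and Schwann cells, 9.03-fold lower (6.62 to 12.4; 27.9 and 3.10 CPM). Flow response genes were at least 2-fold lower in 6 of 12 cases and higher in 0 (median -0.87, percentile 0.01), or lower in 3 with classes weighted equally. Klf2 and Klf4, transcription factors induced by laminar flow, were 3.39-fold (3.32 to 3.47) and 4.16-fold lower (4.03 to 4.30). Klf2 and Klf4 are also raised by tissue dissociation, and the flow and immediate early lists are not fully separate readings.

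Metabolism and the response to low oxygen were read next. Of 13 glycolysis genes 1 was at least 2-fold higher, 1 lower and 11 between (median 0.46, percentile 96.6). The higher one was Pgk1, phosphoglycerate kinase (2.36-fold, 2.11 to 2.65), and the lower one Pfkfb3, an activator of glycolysis in sprouting endothelium (6.54-fold, 5.67 to 7.55). Fatty acid handling had 5 of 13 at least 2-fold lower and 0 higher (median -0.46, percentile 0.605), with Aqp7, a glycerol channel (11.2-fold lower, 8.86 to 14.2), and Lpl, lipoprotein lipase (9.44-fold lower, 7.27 to 12.4), while Fabp5, a fatty acid carrier, was 1.32-fold higher (1.24 to 1.40). Hypoxia response genes were at least 2-fold lower in 7 of 16 cases and higher in 0 (median -0.92, percentile 0), but lower in 2 as a mean of per-cell CPM or with classes weighted equally and in 3 over all barcodes. Slc2a1 and Pfkfb3 were 2 of the 7, and Hif1a, the oxygen-sensing transcription factor itself, was 1.40-fold higher (1.30 to 1.51).

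Endothelial cells recruit leukocytes and can present antigen. Of 17 genes of leukocyte adhesion and chemokines 3 were at least 2-fold higher, 1 lower and 13 between (median 0.46, percentile 99.6), but the median was -0.00 in cells with Xist and no Y-linked UMI, and the count of 3 ran from 1 with a mean of at least 50 CPM required to 9 over all barcodes. The neutrophil growth factor gene Csf3 was 13.8-fold higher (8.70 to 23.4; 3.90 and 53.9 CPM) and the neutrophil chemokine gene Cxcl2 8.91-fold higher (5.6 to 15.1), while Cx3cl1, a membrane-bound chemokine, was 5.23-fold lower (4.42 to 6.20). The adhesion receptor genes Icam1 and Sele, which arrest leukocytes on the vessel wall, were 1.39-fold (1.31 to 1.47) and 1.62-fold higher (1.44 to 1.83), and Vcam1, a related receptor, was 1.79-fold lower (1.69 to 1.90). Interferon response genes were at least 2-fold lower in 18 of 24 cases and higher in 0 (median -1.59, percentile 0), or lower in 11 with classes weighted equally. Ifit3 and Ifit1, which bind viral RNA or its sensors, were 14.1-fold (11.8 to 16.8) and 9.40-fold lower (8.32 to 10.6), and Isg15, a ubiquitin-like modifier, 6.41-fold lower (5.98 to 6.87), whereas Ifitm3, which blocks viral entry, was level at 3128 and 3010 CPM. Of 16 antigen presentation genes 8 were at least 2-fold lower and 0 higher (median -0.94, percentile 0). The count of 8 was 4 as a mean of per-cell CPM or with a mean of at least 50 CPM required, 3 with classes weighted equally and 2 over all barcodes. Without the shallower cells it was near 8 again by per-cell means and by equal weights. The MHC class II genes stood out, with Cd74, the invariant chain (28.8-fold lower, 21.3 to 39.7; 70.4 and 2.45 CPM), and H2-Ab1, a class II beta chain (48.7-fold lower, 27.6 to 93.7), while B2m, the light chain of MHC class I, was 1.32-fold lower (1.28 to 1.35). Lymphoid markers, led by the B cell gene Cd79a, were also lower in these endothelial cells (12.8 and 2.40 CPM, 5.33-fold). The cells had been sorted as CD45-negative and tdTomato-positive, a gate meant to remove B cells. Still, 4 intact EC_PROLIF cells had barcodes shared at similar depth, a set with lymphoid markers at 6352 CPM in the intact library. Whether RNA of immune cells added to the intact values of these lists was not tested.

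Immediate early and dissociation response genes were at least 2-fold lower in 14 of 26 cases and higher in 0 (median -1.14, percentile 0), or lower in 9 with classes weighted equally. Egr1 and Fos, transcription factors induced within minutes of stimulation, were 5.54-fold (5.37 to 5.72; 1891 and 341 CPM) and 3.24-fold lower (3.18 to 3.30; 4218 and 1303 CPM). The stress-inducible HSP70 genes Hspa1a and Hspa1b were 7.80-fold (6.98 to 8.72) and 6.80-fold lower (5.95 to 7.78), although this pair is nearly identical in sequence and reads may be split between them. Hspa8, the constitutive HSP70, was 1.37-fold higher (1.34 to 1.41). The control list of sex-linked genes had 1 of 3 at least 2-fold higher and 1 lower (median -0.99, percentile 2.10). Both libraries came from tissue digested at 37 degrees C, a step that itself induces immediate early genes.

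**Figure D3:**
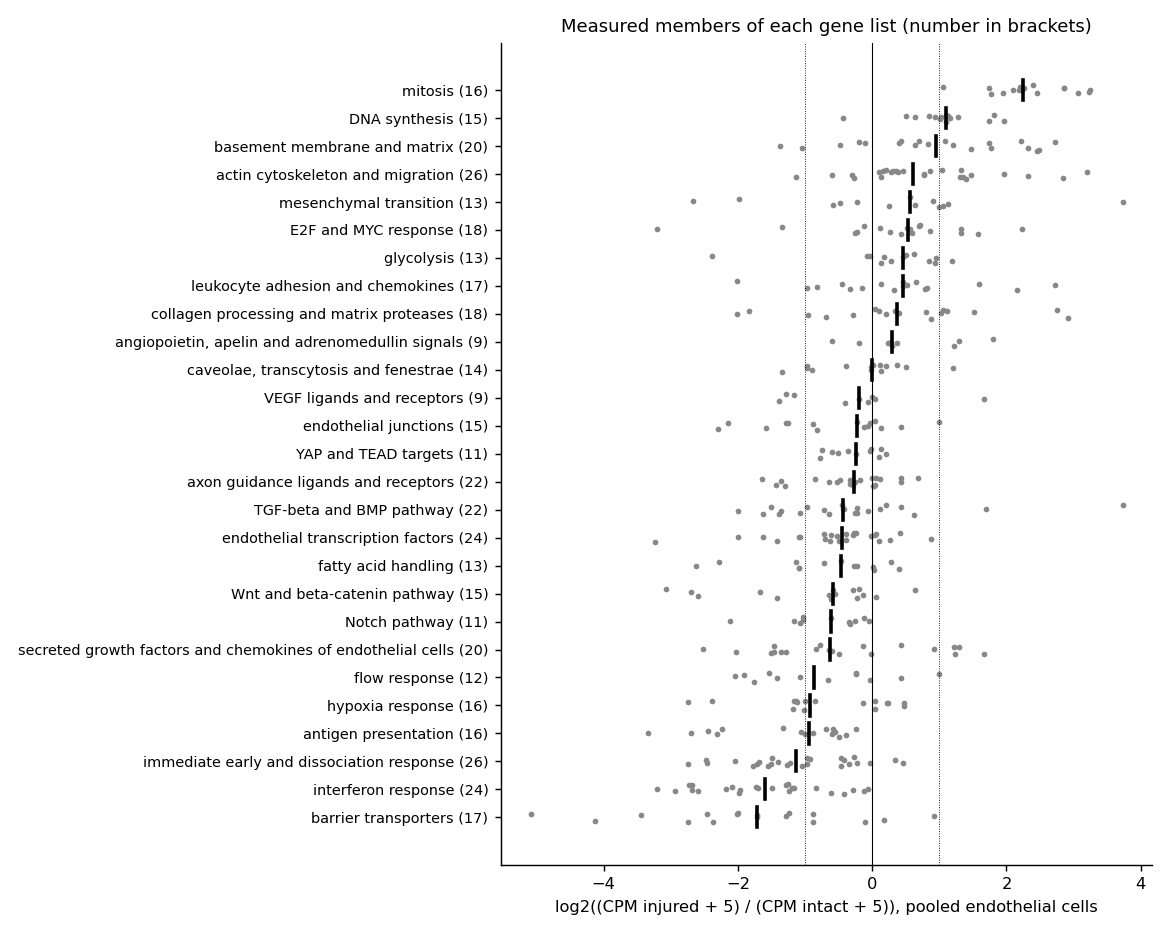
Log2 ratio of injured to intact CPM (5 CPM added to both) for each measured member of 27 gene lists in pooled endothelial cells (dots; black tick, list median; dotted lines, 2-fold either way), with no error bars. Medians ran from 2.25 for mitosis to -1.72 for barrier transporters.

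The third question was what share of endothelial cells expressed mitotic genes. The G2/M list holds genes whose transcripts accumulate as cells prepare to divide. A cell with UMIs of at least 2 different G2/M genes was called positive, after every cell of 3000 or more UMIs was thinned to 3000 UMIs. Positive cells were 1.24% of intact endothelial cells (6 of 482, interval 0.458 to 2.69%, median depth 6454 UMIs) and 13.5% of injured cells (165 of 1223, 11.6 to 15.5%, median depth 12193 UMIs). The thinning left out 336 intact and 99 injured cells below 3000 UMIs. Without thinning the shares were 3.79% (31 of 818) and 29.7% (392 of 1322), and 1.53% (11 of 718) and 30.8% (392 of 1274) when shallower cells were left out too. EC_VEN-PV+ had 0 positive cells of 166 intact (which allows a share of up to 1.81%, median 6033 UMIs) and 1 of 354 injured (0.282%, median 10432.5 UMIs). Dividing cells had a label of their own, EC_PROLIF, so the low share in EC_VEN-PV+ does not measure the background of the call. Within EC_PROLIF the positive share was 66.7% of intact (4 of 6) and 89.2% of injured cells (140 of 157). Leaving out EC_PROLIF gave 0.210% (1 of 476) and 3.75% (40 of 1066). Each set of cells was thinned by its own random draw, so the positive cells of the parts do not add up to the totals above. Injured EC_TIP cells were positive in 9.47% of cases (9 of 95), EC_ART in 5.34% (7 of 131, against 0 of 60 intact, which allows up to 5%) and EC_CAP-PV- in 2.82% (2 of 71, against 0 of 59, which allows up to 5.08%). Injured cells labelled EC_IMMAT were positive in 5.51% (14 of 254) and EC_VEN-PV- in 2.59% (3 of 116). None were positive among injured EC_BAR (0 of 33) and EC_CAP-PV+ cells (0 of 12). With the S phase list, whose genes act in DNA replication, the shares were 16.6% of intact (80 of 482) and 29.0% of injured cells (355 of 1223), so the size of the difference depended on the list.

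The fourth question was whether the pooled differences were also present within the authors' classes. Pooled values mix the classes, so a gene of a class that is less common in the injured library would look lower in the pool with no difference inside any class. Genes were ranked only in classes with at least 50 cells in both libraries and matching markers. Of the 12 higher and 12 lower genes named above, 10 and 12 were at least 2-fold different the same way within EC_ART (93 and 144 cells), 5 and 11 within EC_BAR (181 and 83), 9 and 7 within EC_CAP-PV- (129 and 76) and 8 and 9 within EC_VEN-PV+ (218 and 362). For EC_BAR they were 6 and 4 as means of per-cell CPM, which give its 47 shallower injured cells full weight. Without those cells the summed counts gave 5 and 11 again. The cells of these classes were also part of the pools from which the genes were picked. Some agreement was therefore built in, and the counts are no independent support. In an unsupervised clustering of both libraries, cluster 6 held 55 of 93 intact and 83 of 144 injured EC_ART cells. Of the other EC_ART cells, 62 lay in cluster 7, which had 12 intact and 140 injured cells of all classes. Another 34 lay in cluster 1, which had 276 intact and 50 injured cells. The EC_ART cells outside cluster 6 were thus not alike in the 2 libraries. EC_BAR was mostly cluster 1 (180 of 181 intact and 47 of 83 injured cells), but without the shallower cells its injured cells were mostly cluster 6 (21 of 36), the cluster of most EC_ART cells. EC_CAP-PV- was mostly cluster 4 in intact and cluster 3 in injured nerve, and EC_VEN-PV+ was mostly cluster 2 in intact and cluster 0 in injured nerve.

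In arterial cells Ctla2a, a cathepsin inhibitor, was 35.8-fold higher (25.9 to 50.9; 61.2 and 2187 CPM), and Lrg1, a glycoprotein that promotes vessel growth, 19.7-fold higher (10.7 to 41.4). Nid1, the basement membrane protein nidogen, was 30.8-fold higher from 3 intact UMIs (10.4 to 150.0), and Nts, the peptide neurotensin, 91.4-fold higher from 1 intact UMI (16.3 to 3622). That UMI came from a shallower cell, and without such cells Nts had 0 intact UMIs and was at least 30.3-fold higher, taking 3 counts in place of 0. Lower in EC_ART were Mt1, the metal-binding metallothionein (40.3-fold, 23.8 to 73.5), Alpl, alkaline phosphatase (31.0-fold, 17.8 to 58.2), Cytl1 (27.7-fold, 20.5 to 38.2), Cp, the copper protein ceruloplasmin (21.4-fold, 11.9 to 42.0), and Ifi27l2a, an interferon-inducible gene (13.5-fold, 11.2 to 16.4). In EC_BAR the genes with the highest ratios were Igfbp4, a binding protein for insulin-like growth factors (48.0-fold, 35.2 to 67.0; 31.6 and 1516 CPM), Plvap (41.2-fold, 26.7 to 66.9), Lrg1 (38.2-fold, 27.6 to 54.3), Aqp1, a water channel (33.5-fold, 23.8 to 48.3), and Stmn2, a microtubule regulator (132-fold, 35.2 to 1106, from 2 intact UMIs). Lower in EC_BAR were Slc7a5 (18.3-fold, 8.80 to 45.7), Car4 (9.28-fold, 6.14 to 14.7), Acta2 (6.74-fold, 5.12 to 9.05), Fmo2 (6.69-fold, 4.23 to 11.2) and Slco1a4 (5.99-fold, 4.73 to 7.70). Without the 47 shallower injured EC_BAR cells, Car4 had 0 UMIs in injured EC_BAR, Slc7a5 was 28.9-fold lower, Acta2 14.7-fold lower and Slco1a4 9.50-fold lower.

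EC_CAP-PV- cells of injured nerve were higher in Col18a1 (41.2-fold, 18.8 to 113), Fam167b (22.0-fold, 10.0 to 60.6), Tmem252 (21.2-fold, 11.4 to 44.5) and Chga, which had 0 intact UMIs and was at least 20.2-fold higher by the same rule. They were lower in Rgs5, a regulator of G-protein signals best known from pericytes (28.1-fold, 13.1 to 71.9), Slc28a2, a nucleoside transporter (24.7-fold, 11.4 to 63.4), Fmo1 (17.5-fold, 9.78 to 33.9), Xdh, xanthine dehydrogenase (13.6-fold, 8.74 to 22.2), and Timp4, a protease inhibitor (13.5-fold, 10.2 to 18.1). In EC_VEN-PV+ the higher genes included 3 of the pooled 12: Mest (29.4-fold, 15.9 to 61.6), Tgfbi (20.8-fold, 14.6 to 30.7), Marcksl1 (11.7-fold, 8.18 to 17.5), Lgals1, the lectin galectin-1 (10.5-fold, 7.40 to 15.4), and Col4a1 (9.55-fold, 8.45 to 10.8). Cytl1 was 469.7-fold lower there (200.2 to 1451; 494 and 1.05 CPM). Cd74 was 84.0-fold lower (46.2 to 170.3), Fmo1 27.6-fold (19.5 to 40.2), Fmo2 23.9-fold (19.7 to 29.1) and Pltp, which transfers phospholipids between lipoproteins, 17.1-fold lower (13.7 to 21.6).

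Some genes differed in 1 class and not in another, shown here without the shallower cells for 4 genes chosen after their values were seen. EC_BAR then had 36 injured cells and EC_VEN-PV- 44 intact cells, fewer than the 50 asked for above. Plvap was 17.0-fold higher in EC_ART (36.5 and 620 CPM), 45.7-fold in EC_BAR (16.2 and 738 CPM) and 16.8-fold in EC_VEN-PV- (44.7 and 752 CPM), the classes in which it was low in intact nerve. In EC_CAP-PV- it was 3.02-fold higher, and in EC_VEN-PV+, where it was already at 2240 CPM, the ratio was 0.766. Cldn5 was 2.14-fold lower in EC_ART, 2.21-fold in EC_BAR and 9.66-fold in EC_VEN-PV- (3504 and 363 CPM), but level in EC_CAP-PV- (1076 and 1030 CPM) and 1.57-fold higher in EC_VEN-PV+ from 48.3 CPM. Slco1a4 was 9.50-fold lower in EC_BAR, 7.25-fold in EC_ART and 34.5-fold in EC_VEN-PV-. Col4a1 was higher in all 5 classes, from 3.14-fold in EC_CAP-PV- to 9.95-fold in EC_VEN-PV+. In EC_VEN-PV- most intact cells were in cluster 1 and most injured cells in cluster 10.

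Medians of 6 lists had the pooled sign in all 4 classes, while some others did not, such as axon guidance at 0.10 and YAP and TEAD targets at 0.08 in EC_ART. For basement membrane and matrix they were 1.76 in EC_ART, 1.32 in EC_BAR, 1.09 in EC_CAP-PV- and 0.95 in EC_VEN-PV+. Barrier transporters had medians of -1.10, -0.90, -0.79 and -0.57 in the same order. The interferon response stood at -1.56, -0.71, -0.78 and -0.65, and immediate early genes at -1.42, -0.66, -0.72 and -0.77. Antigen presentation was at -0.75, -0.49, -0.89 and -0.69, and leukocyte adhesion at 0.52, 0.83, 0.73 and 0.13. A class named by its markers can hold cells of different origin in the 2 libraries, and that was not resolved here.

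**Figure D4:**
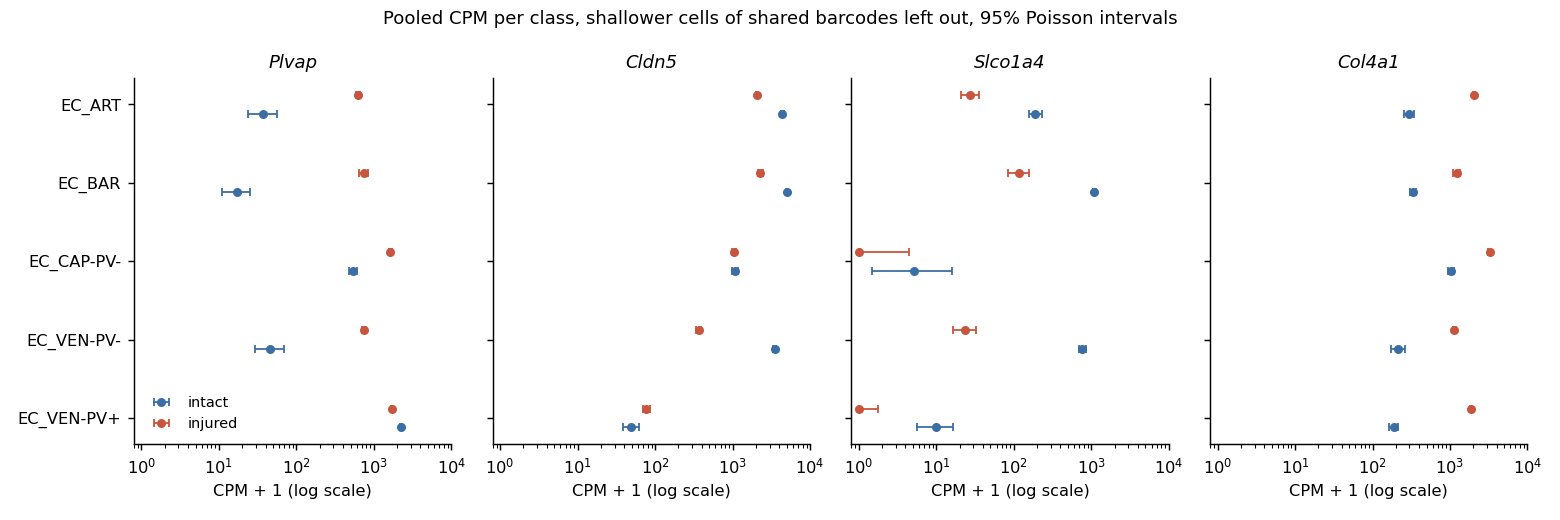
CPM plus 1 (log scale) of Plvap, Cldn5, Slco1a4 and Col4a1 in 5 endothelial classes of the intact and injured libraries without the shallower cells of shared barcodes (error bars, 95% Poisson intervals). Plvap was higher in injured EC_ART, EC_BAR and EC_VEN-PV- and not in EC_VEN-PV+ (ratio 0.766).

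Transcripts of other cell types were mostly lower after injury, and most sets were low among the annotated cells. In intact cells, however, pericyte and smooth muscle markers came near the tip endothelial set (1135 and 1513 CPM). Fibroblast markers, led by the proteoglycan gene Dcn, stood at 250.2 CPM in intact and 81.6 CPM in injured annotated cells, and pericyte and smooth muscle markers at 1135 and 225 CPM. Perineurial markers, a set that includes Slc2a1, were at 637 and 149 CPM, and erythroid markers at 310.1 and 45.3 CPM. Myeloid markers were at 59.9 and 49.5 CPM, lymphoid at 12.8 and 2.37 CPM, and lymphatic endothelial markers at 72.3 and 61.4 CPM. The mast cell set was higher, at 3.99 and 58.9 CPM, and all of it came from Kit, a receptor that endothelial cells can also express. Among endothelial sets, barrier markers were at 6335 and 1101 CPM, tip markers at 1513 and 2768 CPM, and venous markers at 3029 and 3791 CPM.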

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

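The tests of a constant rate and of the best correlated partner were chosen only after the shared barcodes had been seen, and the other tests in this part were planned before their results.

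A barcode is drawn at random from a large pool, so few should recur in 2 separate libraries. Yet 298 barcodes were present in both. Lymphoid transcripts were at 6352 CPM in the intact copies of the 37 shared barcodes of similar depth, although CD45-positive cells had been sorted away and annotated intact cells held 12.8 CPM. Col1a1, a fibrillar collagen gene of fibroblasts, stood at 5433 CPM in injured cells without a class and at 760.2 CPM in intact ones. Lymphatic endothelial markers stood at 4632 CPM in intact cells without a class and at 843 CPM in injured ones. The Col1a1 and lymphatic values lie in cells that the comparisons did not use. Of the shared barcodes, 148 were annotated in both libraries, and 9 intact and 8 injured copies of the 37 were annotated, so these did enter the comparisons.

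The cells labelled EC_TIP, EC_IMMAT or EC_PROLIF in the intact library, and EC_BAR in the injured one, often shared a barcode with a far deeper cell of the other library. Independent cells meeting by chance are argued against, because the own partner was the best correlated deep cell for 100% of shallower cells in both directions, where chance gives 0.0627% and 0.104%. A candidate explanation is that reads were assigned to the wrong library at a constant rate, since the shallower cell's UMIs as a percent of its partner's varied with a coefficient of variation of at most 6.67%, against 38.8 to 41.6% for random pairs. Likewise, shallower intact cells with a female partner held 0 Y-linked UMIs of 80 sex-linked ones (interval up to 4.51%), against 21.5% (259 of 1204) in unshared intact endothelial cells, as molecules of the injured cell would. Tip, immature or proliferating profiles in uninjured nerve also stay open for a smaller number, since 9 intact cells with these labels, 3000 or more UMIs and an unshared barcode remained.

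Immediate early genes respond both to digestion and to signals in tissue, so their lower level in injured endothelium draws attention to handling. The median log2 ratio in fibroblast-like cells was 0.30 (interval 0.26 to 0.38), so the list was not lower in every cell type. Those cells differed widely between the libraries, so a shared drop hidden in them stays open. The sex mix is argued against, with -1.31 in endothelial cells with Xist and no Y-linked UMI. A shift between classes as the whole cause is too, with -0.72 as the highest of EC_ART, EC_CAP-PV- and EC_VEN-PV+. Such a shift as part of the drop stays open, since EC_CAP-PV- and EC_VEN-PV+ were at -0.72 and -0.77, against -1.14 in the pool. A response to digestion that is particular to endothelium stays open, which the median of -0.88 in lymphatic-like cells (20 injured) also allows, as do the animals and the different tissue region (bridge against whole nerve). None of these, nor an effect of the injury itself, was tested apart.

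Interferon response genes are kept on at a low level in many resting vessels, and they were lower in the injured endothelium. In fibroblast-like cells the median was 0.47 (interval 0.32 to 0.70), so the list was not lower in every cell type. Those cells differed widely between the libraries (Col1a1 was 8.76-fold higher), and lymphatic-like cells (20 injured) had a median of -0.58. A shared drop hidden in the fibroblast-like cells therefore stays open. The median was -1.61 in endothelial cells with Xist and no Y-linked UMI, and -0.65 was the highest within the 3 classes, which argues against sex mix and class shift as the whole cause. An effect of the injury itself, the tissue region, and differences in infection or housing between the pooled animals that act on endothelium alone stay open and were not tested apart.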

How the results depend on the processing

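The tests added after the results were seen were leaving out the shallower cells of shared barcodes (alone, with per-cell means, with equal class weights or, for class shares, with those of similar depth), including INTERMEDIATE, and using cells with Xist and no Y-linked UMI only. No paired analysis was possible because each condition had 1 library, and leaving out a replicate was not possible for the same reason. Across 18 alternatives barrier transporters stayed within 9 to 13 members at least 2-fold lower, TGF-beta and BMP genes within 4 to 7 and endothelial transcription factors within 4 to 6, and their medians stayed negative. Over all alternatives, log2 ratios of the 24 named genes moved 202 times, reversed 4 times and stayed near the main value 226 times. Medians of the 28 lists moved 205 times, reversed 7 times and stayed 289 times. Member counts on the higher side moved 25 and stayed 98 times, and on the lower side 29 and 169 times. Marker CPM moved 62 and stayed 18 times, class shares moved 21, reversed 1 and stayed 34 times, and G2/M percentages moved 9 and stayed 5 times. In the rest of this part, H and L are members at least 2-fold higher and lower. The main values were Notch L 5, Wnt L 5, secreted factors L 7, matrix H 10, hypoxia L 7, leukocyte H 3, antigen L 8, interferon L 18, immediate early L 14, flow L 6, mesenchymal H 3, actin H 10, DNA synthesis H 10, mitosis H 16 and E2F and MYC H 4. With all barcodes they were Notch L 2, secreted L 2, hypoxia L 3, leukocyte H 9, antigen L 2 and mesenchymal H 5, where cells of other types enter. Scaling without mitochondrial, ribosomal protein and the 50 top genes gave Notch L 3. The mean of per-cell CPM gave Notch L 1, matrix H 6, hypoxia L 2, antigen L 4, mesenchymal median -0.0364, actin H 6, DNA synthesis H 1, mitosis H 7 and E2F and MYC H 0. Thinning to 3000 UMIs gave Notch L 3 and DNA synthesis H 2. A pseudocount of 20 gave Notch L 1, secreted L 4, hypoxia L 4 and DNA synthesis H 2, since it shrinks ratios of low genes. A mean CPM of at least 50, which leaves fewer genes and moves the median of all genes to 0.11, gave Wnt L 2, secreted L 2, leukocyte H 1, antigen L 4, DNA synthesis median -0.43 and H 0, and sex-linked median 1.66. That DNA synthesis median rests on very few genes, and the sex-linked one equals the log2 ratio of Xist alone (1.66). With G2/M cells left out, values were Notch L 3, leukocyte H 5, DNA synthesis H 1, E2F and MYC H 2, Hist1h2ap -0.000499 and Pclaf -0.46, as removing dividing cells must lower their genes. Classes weighted equally gave Notch L 1, Wnt L 3, secreted L 3, matrix H 2, hypoxia L 2, antigen L 3, interferon L 11, immediate early L 9, flow L 3, mesenchymal median -0.0788 and H 1, actin H 2, DNA synthesis H 0, mitosis median -0.0170 and H 1, E2F and MYC H 0, and Hist1h2ap -0.0914. Matrix H returned from 2 to 10 once shallower cells of shared barcodes were left out. EC_IMMAT, EC_PROLIF and EC_TIP then had too few intact cells and left the equal weights too, so the 2 changes cannot be told apart. Likewise, with shallower cells out, actin H and antigen L were near their main values by per-cell means and by equal weights. The mesenchymal median did not reverse in either setting then. With per-cell means and the shallower cells out, values were Notch L 2, hypoxia L 4, leukocyte H 6 and DNA synthesis H 4. With equal class weights and those cells out, they were Notch L 3, Wnt L 3, hypoxia L 2, leukocyte H 6, DNA synthesis H 0, E2F and MYC H 2 and Pclaf -0.0240. Xist-only cells gave leukocyte median -0.000852 and sex-linked median 0.73. Ratios of class shares from own clusters, each named by its largest class, were 2.22 for EC_ART, 0.109 for EC_BAR, 0.00938 for EC_CAP-PV- and 21.3 for EC_PROLIF. In cells of at least 3000 UMIs they were 0.107 for EC_BAR, 99.9 for EC_IMMAT, 10.3 for EC_PROLIF, 18.7 for EC_TIP, 0.839 for EC_VEN-PV+ and 1.04 for EC_VEN-PV-. Under 5% mitochondrial UMIs gave 0.173 for EC_BAR, 2.09 for EC_IMMAT, 1.32 for EC_VEN-PV+ and 0.677 for INTERMEDIATE. Without shallower cells they were 0.112 for EC_BAR, 36.5 for EC_IMMAT, 8.26 for EC_PROLIF and 14 for EC_TIP, and with similar-depth cells out too 0.111, 36.2, 12.9 and 13.9. The G2/M percentage was 19.0 in injured cells thinned to 5000 UMIs, 3.79 and 29.7 with no thinning, 5.6 and 27.1 with at least 1 gene, 11 in injured cells with at least 3 genes, 16.6 and 29.0 with the S phase list, and 30.8 in injured cells with no thinning and no shallower cells. Of the 24 named genes, EC_BAR had 10 at least 2-fold the same way by per-cell means against 16. Per-cell means gave full weight to the 47 of its 83 injured cells that were shallower partners. EC_IMMAT, for which no marker set existed, had 14 when thinned and 16 without shallower cells (4 intact cells), against 6. For every difference with no reason given here, the cause was not tested. Mitosis has no value with a mean of at least 50 CPM, with G2/M cells left out, or with equal class weights and no shallower cells, where too few members were measured. EC_CAP-PV+, EC_TIP and INTERMEDIATE held no cluster as largest class, and the cluster of EC_VEN-PV- had 0 intact cells, so own clusters give no ratio for them. Depth limits the intact library most, where 336 of 818 endothelial cells had under 3000 UMIs.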

Other observations

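The groups of cells in this part were made after the data were seen, and no test was planned for them.

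Fibroblasts fill the bridge of a healing nerve and lay down its collagen. Among the cells without a class 433 intact and 286 injured ones were fibroblast-like, at median depths of 5884 and 10524 UMIs. TdTomato in them was at 44.8 and 41.0 CPM and Pecam1 at 9.39 and 54.1 CPM. Col1a1, the main chain of collagen I, was at 1012 and 8867 CPM, 8.76-fold higher (8.45 to 9.08), while the small proteoglycan gene Dcn was at 12553 and 7929 CPM. Cthrc1, a secreted protein of activated fibroblasts, had 1 UMI in intact cells and was at 358 CPM in injured ones (ratio 1180, 212 to 46655). Vcan, a matrix proteoglycan, was 124-fold higher, and Ccl2, a monocyte chemokine, 18.4-fold higher. Lower were Rbp4, a retinol carrier (19.8-fold), and Ndrg1, a stress-response protein (10.3-fold). Of 22 collagen processing genes 15 were at least 2-fold higher and 1 lower, of 23 matrix genes 14 higher and 2 lower, and of 13 leukocyte adhesion and chemokine genes 9 higher and 0 lower. Of 17 mitosis genes 17 were at least 2-fold higher.

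Lymphatic vessels of nerve lie in its outer sheath. Lymphatic-like cells numbered 102 in intact and 20 in injured nerve (13.6% and 3.40% of the cells without a class), and so few injured cells allow only a rough reading. Ccl21a, the chemokine by which lymphatics draw dendritic cells, was at 3147 CPM in all intact cells without a class and 334 CPM in injured ones. In lymphatic-like cells 18 of 18 mitosis and 16 of 18 DNA synthesis genes were at least 2-fold higher. The immediate early list had a median of -0.88, with 9 of 25 genes at least 2-fold lower and 1 higher, and the interferon list a median of -0.58, with 5 of 17 lower and 0 higher. Both medians had the sign seen in blood endothelium and not that seen in fibroblast-like cells.

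Other values stood outside the comparisons. Among endothelial cells of at least 3000 UMIs, 39.2% of intact (189) and 76.9% of injured cells (940) had Xist and no Y-linked UMI, and 35.3% (170) and 16.4% (201) the reverse. The 37 shared barcodes of similar depth had near-equal profiles in the 2 libraries, with lymphoid markers at 6352 and 5941 CPM, Trbc2, a T cell receptor chain, at 2269 CPM and S100a9, a neutrophil protein, at 2117 CPM in the intact copies, from a median of 859 UMIs.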
